A study of Rattus norvegicus with 2 samples.

How the data were processed

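RNA was measured by sequencing in 2 libraries of H9c2 cells, a cell line derived from embryonic rat heart. One library came from cells transfected with an empty vector and 1 from cells transfected with a plasmid for Cacnb4. Total RNA was purified with a column kit and made into Illumina libraries, per the labels' protocols. Groups were taken from the sample titles. Each group held 1 library, so no difference had a replicate check and no p-value was computed across genes.

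The deposited read counts per library gave raw, mappable and unmapped reads, and the file's footnote states that the 3' adaptor was removed and reads under 10 bases were left out. TopHat 1.4.1 and genome build rn4 are named in the submitters' processing notes. The program that estimated transcript levels is not given in the sources used here. The deposited expression table held 32767 transcripts with 1 value per library, and its IDs were numbered up to 32790, so that 23 numbers were not analysed here. Its header does not name the unit. The values were not whole, their sums were 9226668 in the empty vector library and 10220201 in the Cacnb4 library, and the table's layout is that of a per-transcript FPKM comparison, so the authors' values were read as FPKM, fragments scaled to transcript length and to the mapped reads of the library. The authors' deposited table also gave a log2 fold change, a p-value and a q-value per transcript and a mark for significance. That mark stood on the 228 transcripts with q below 0.05. These tests compare the reads of these 2 libraries, not the conditions. The deposited pathway table gave counts of genes, a fold enrichment ratio, a p-value and a Benjamini-adjusted p-value per KEGG pathway, per the file headers.

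FPKM was summed over the transcripts of each gene symbol, which gave 16783 symbols. Left out of this step were 13533 transcripts with no gene name and 17 whose names had the form of a date. A gene was called measured at 1 FPKM or more in at least 1 library, which held for 9539 genes. The log2 ratio was log2((FPKM Cacnb4 + 1)/(FPKM empty vector + 1)), which understates the difference of low genes, and a gene was counted as higher or lower at 2-fold or more on that scale. Statements that a gene lay at, beyond, within or under 2-fold are on that scale, and ratios given as times are of the FPKM values themselves. The design foresaw leaving out transcripts with a failed estimate, but the table used here has no column for this. Of the symbols, 16315 matched a symbol or a unique synonym of the RefSeq annotation of assembly GRCr8, which was used for names and, for LOC252890, the type of gene. Coordinates are those of the expression table on rn4. The table does not say whether its starts count from 0 or 1.

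26 gene lists, the size rule, the rule for named genes and the alternative settings were fixed before the data were examined. The series title, which names antiviral factors, was known by then and was the reason given for the interferon-stimulated list. For each list with at least 3 measured members, the median log2 ratio was placed by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 libraries. The 95% interval given with a median is the binomial order-statistic interval for that median over the list's members. It treats members as independent, which genes regulated together or sharing sequence are not. It gives neither the range of single genes nor the spread between cultures. Named were Cacnb4, the 12 genes with the highest and the 12 with the lowest log2 ratio, up to 4 members with the largest absolute log2 ratio in each list (up to 8 in the interferon-stimulated, nucleic acid sensing and calcium channel lists), and up to 10 genes of the authors' significant transcripts with the largest finite fold. After the data were seen, the 12 highest and lowest genes without microRNA precursors were added, and other genes named outside this rule are said to be so. Some genes that the rule names are not reported here.

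Alternatives were a pseudocount of 0.1 or 5 FPKM, no minimum or a minimum of 5 FPKM, the transcript with the highest mean in place of the sum, a rescaling that set the median ratio of genes at 5 FPKM or more in both libraries to 1, and for the authors' calls a q below 0.01 or a minimum of 1 FPKM. Leaving out microRNA precursors was added after the data were seen. The size rule was tested on simulated data with 200 of 9369 genes changed and an assumed noise SD of 0.15 on the log2 scale in each library. It counted 42.0% of the genes set to 2-fold and 100% of those set to 4-fold. All genes set to change had a mean of 5 FPKM or more over the 2 libraries. The simulation does not cover changes in lower genes, nor short features, whose ratios spread more widely. Reads per gene were not worked back from FPKM, so no counting interval is given. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.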

Results

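Transcript levels were compared between H9c2 cells that received an empty vector and H9c2 cells that received a plasmid for Cacnb4, which encodes the beta4 auxiliary subunit of voltage-gated calcium channels. The series asks how raising this subunit alters expression as a whole, and its title names antiviral factors. There was 1 library per group, so none of the differences below has a replicate check. The empty vector library held 15258174 raw reads, of which 13569897 were mappable. The Cacnb4 library held 16925364 raw reads, of which 14939784 were mappable. Unmapped reads came to 14.6% of the mappable reads in the empty vector library and 12.7% in the Cacnb4 library.

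Cacnb4 itself was listed at 4.37 FPKM in the empty vector library and at 6266 FPKM in the Cacnb4 library, 1433 times as much, with a log2 ratio of 10.19. Its transcript lies on chromosome 3 from 33934477 to 34072070 in rn4. It was the gene with rank 6 by FPKM in the Cacnb4 library and rank 7622 in the empty vector library, and it held 0.951% of the FPKM of named transcripts after transfection. The values do not separate transcripts of the plasmid from those of the cells' own gene. The other measured calcium channel subunits stayed within 2-fold, 7 of the list's 8 measured members. Cacnb3, another beta subunit, was at 50.3 and 55.1 FPKM in the empty vector and Cacnb4 libraries. Cacnb1 was at 9.18 FPKM in the Cacnb4 library, 1.15 times its value in the other, and Cacnb2 was at 1.70 and 1.74 FPKM. Cacna1c, the pore subunit of the Cav1.2 channel, was at 1.16 and 1.11 FPKM. Cacna2d1 was at 19.3 and 19.7 FPKM, Cacng1 at 9.11 and 6.84 FPKM, and Cacna2d4 at 1.34 and 0.862 FPKM. With Cacnb4 included, the list's median log2 ratio was 0.02, at percentile 72.8 of matched random lists.

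Among the fixed lists, the interferon-stimulated genes had the highest median log2 ratio. Of 47 measured members of the list of interferon-stimulated antiviral effectors, 42 were at least 2-fold higher in the Cacnb4 library, 0 were 2-fold lower, and all 47 had a log2 ratio above 0. The median log2 ratio was 2.23 (95% interval 1.94 to 2.62), above all 10000 matched random lists. Ifit3, which belongs to a family of RNA-binding antiviral proteins, was at 22.3 FPKM in the empty vector library and 428 FPKM in the Cacnb4 library, 19.2 times as much. Isg15, a ubiquitin-like modifier, was at 18.0 and 285 FPKM. Zbp1, a sensor of Z-form nucleic acid, was at 4.29 and 67.5 FPKM. Bst2, the tetherin that holds budding virions at the cell surface, was at 3.47 and 50.1 FPKM. Ifit2 was at 10.5 and 133 FPKM, Ifit1 at 26.2 and 290 FPKM, and Ifi47 at 0.685 and 17.3 FPKM. Oasl2 was at 3.17 FPKM in the empty vector library and 16.7 times that in the Cacnb4 library. The authors' deposited table marked 36 genes of this list as significant between these 2 libraries, and it gave Ifit3, Isg15, Zbp1, Ifit2, Ifit1 and Ifi47 a q-value of 0. Members of the Ifit, Oas and Gbp families share sequence, so their single values are uncertain.

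**Figure D1:**
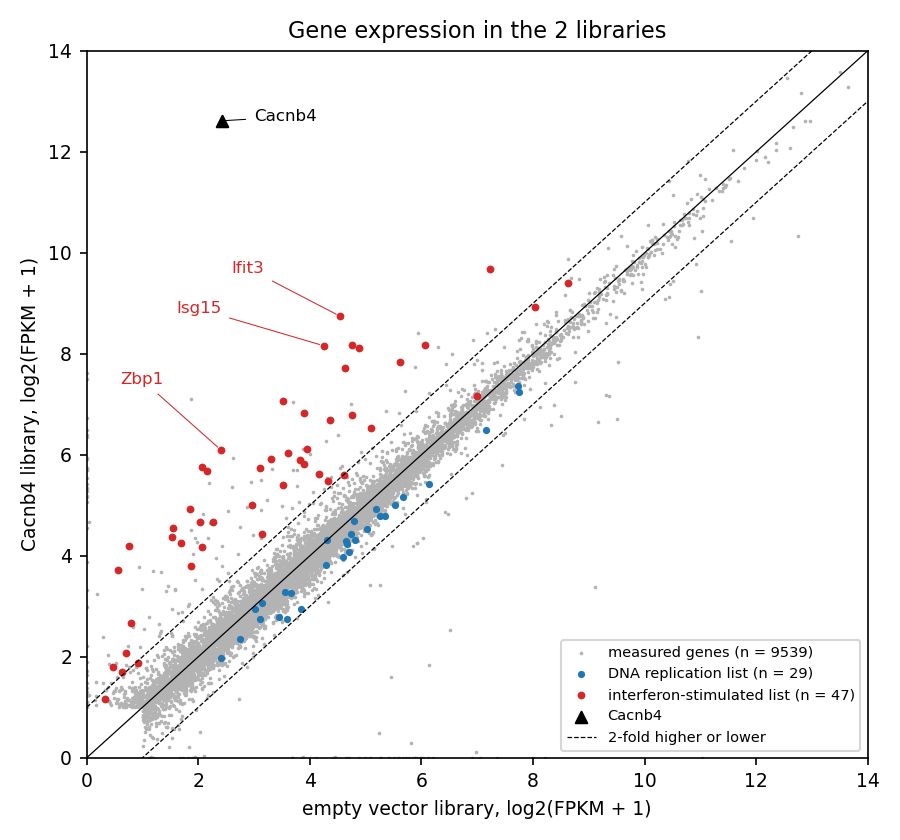
Each point is 1 of 9539 measured genes, with log2(FPKM + 1) in the empty vector library on the x axis and in the Cacnb4 library on the y axis. Dashed lines mark 2-fold. The 47 interferon-stimulated genes (red) lie above the diagonal, Cacnb4 (triangle) stands apart at 4.37 against 6266 FPKM, and 28 of the 29 DNA replication genes (blue) lie below the diagonal.

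Sensors of foreign nucleic acid and factors that relay interferon signals were higher for part of their list. Of 28 measured members, 7 were at least 2-fold higher, 0 were at least 2-fold lower, and 5 had a log2 ratio below 0. The median log2 ratio was 0.30 (95% interval 0.08 to 0.89), above all matched random lists. The 3 cytosolic RNA sensors of the RIG-I family were among the 7 higher genes. Dhx58 was at 3.60 FPKM in the empty vector library and 42.4 FPKM in the Cacnb4 library, Ifih1 at 2.66 and 21.7 FPKM, and Ddx58, which encodes RIG-I, at 6.68 and 43.2 FPKM. The transcription factor Irf7 was at 60.4 and 341 FPKM, and Stat2 at 25.7 and 127 FPKM. Trim25, a ubiquitin ligase acting on RIG-I, was at 3.99 and 14.5 FPKM, and Socs1, a feedback inhibitor of cytokine receptors, at 1.16 and 5.93 FPKM. The authors' deposited table marked 6 of these 7 and gave Socs1 a q-value of 0.248. Irf9, a transcription factor that binds Stat2, was at 24.4 and 46.3 FPKM, below 2-fold.

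Of 35 listed interferons, cytokines and chemokines, 14 were measured and 5 of these were at least 2-fold higher. The median log2 ratio was 0.40 (95% interval 0.06 to 1.36), above all matched random lists, but 0.06 with no filter on low values. The authors' deposited table marked 1 of them, Cxcl10. Cxcl10, a chemokine induced by interferon, was at 12.1 FPKM in the empty vector library and 131 FPKM in the Cacnb4 library. The gene of interferon beta, Ifnb1, was at 0.671 and 3.64 FPKM, and the authors' deposited table gave it a q-value of 0.357. Cxcl11, which shares a locus with Cxcl10 in the table, was at 0.433 and 2.68 FPKM, and Ccl2 at 0.941 and 3.60 FPKM. Il15, chosen after its value was seen to complete the 5, was at 1.44 and 4.31 FPKM. None of 11 measured NF-kappa B targets was 2-fold different, with a median log2 ratio of -0.01 at percentile 55.9. Ptgs2 had the largest log2 ratio there on the FPKM + 1 scale, at 14.4 and 20.4 FPKM. Of 9 measured complement and acute phase genes, 1 was 2-fold higher, C1s at 4.03 and 10.7 FPKM, and the list's median of 0.21 (95% interval -0.02 to 0.71) was at percentile 98.2.

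Genes of antigen presentation on MHC class I were higher as a group, with a median log2 ratio of 1.37 (95% interval 0.95 to 1.93) above all matched random lists. Of 33 measured members, 22 were at least 2-fold higher, 0 were at least 2-fold lower, and 2 had a log2 ratio below 0. Psmb9, a subunit of the immunoproteasome, was at 0.137 FPKM in the empty vector library and 8.44 FPKM in the Cacnb4 library. The class I heavy chain gene RT1-A1 was at 3.23 and 27.3 FPKM, RT1-A2 at 8.97 and 51.8 FPKM, and RT1-CE14 at 3.61 and 24.1 FPKM. The authors' deposited table marked 7 genes of this list. RT1-CE14, a sum of 7 transcripts at 3 loci, was not among them. The RT1 genes are near copies of each other and RT1-A1 and RT1-A2 share a locus in the table, so reads can be split between them and the count of 22 is not one of independent genes. B2m, the class I light chain and a commonly used reference gene, was at 411 and 727 FPKM.

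**Figure D2:**
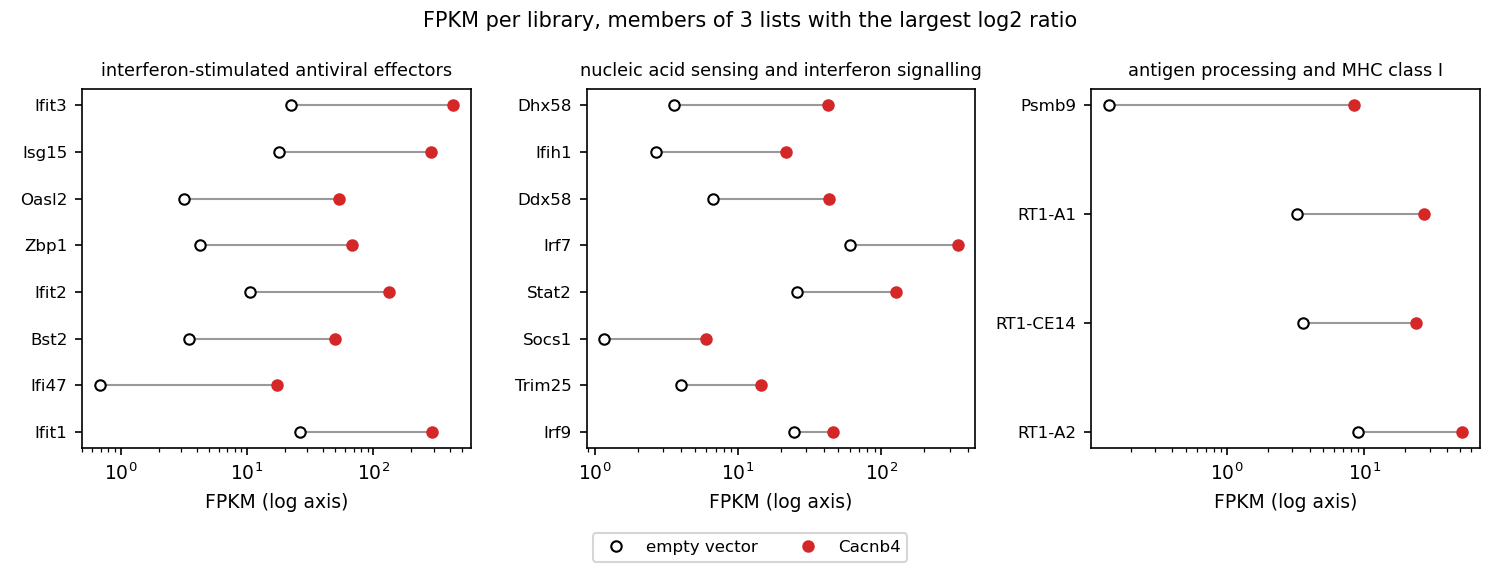
FPKM on a log axis in the empty vector library (open circles) and the Cacnb4 library (red circles), 1 library each, for the 8, 8 and 4 members with the largest log2 ratio in 3 fixed lists. Every gene shown was higher in the Cacnb4 library, with log2 ratios from 0.90 for Irf9 to 4.20 for Ifit3.

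Genes of cell division were lower by a small amount in nearly all members. Of 29 measured DNA replication genes, 28 had a log2 ratio below 0, with a median of -0.46 (95% interval -0.52 to -0.36). Of 32 measured mitosis and cell cycle genes, 30 were below 0, with a median of -0.33 (95% interval -0.40 to -0.23). Both medians lay below all 10000 matched random lists, 0 members reached 2-fold, and the authors' deposited table marked 0 of them. Fen1, the flap endonuclease of lagging-strand synthesis, was at 13.2 FPKM in the empty vector library and 6.70 FPKM in the Cacnb4 library. Gins1 was at 11.1 and 5.75 FPKM, Mcm6 of the replicative helicase at 69.2 and 41.7 FPKM, and Cdc6 at 9.91 and 5.89 FPKM. Cyclin E1, Ccne1, was at 31.2 and 18.0 FPKM, Aurkb at 36.2 and 23.6 FPKM, Mad2l1 at 23.7 and 15.8 FPKM, and Ccnb1 at 69.6 and 47.4 FPKM.

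Among stress lists, the unfolded protein and integrated stress response list had a median log2 ratio of 0.30 (95% interval -0.05 to 0.46), with 9 of 27 members below 0. The list of p53 targets and apoptosis genes had one of 0.18 (95% interval -0.07 to 0.50), with 8 of 26 below 0. Both medians lay above all matched random lists, both intervals include 0, and 1 member of each list was at 2-fold. Atf3, a transcription factor induced by stress, was at 12.1 FPKM in the empty vector library and 50.8 FPKM in the Cacnb4 library. Chac1 was at 23.5 and 47.3 FPKM, Trib3 at 58.7 and 116 FPKM, and the folding factor Sdf2l1 at 23.1 and 14.1 FPKM. Casp12 was at 15.6 and 37.2 FPKM, Casp4 at 30.6 and 59.2 FPKM, and Bcl2 at 0.709 and 2.23 FPKM. The heat shock list had a median of -0.16 at percentile 4.55, with Hspa8 at 1486 and 1103 FPKM. Immediate early genes had a median of -0.04 at percentile 45.4, and Klf2 there was at 27.9 and 56.7 FPKM.

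Muscle and matrix lists held 0 members at 2-fold on the FPKM + 1 scale. Skeletal muscle differentiation genes had a median log2 ratio of 0.15 (95% interval -0.0032 to 0.29) over 23 measured members, at percentile 99.9. Myh3, the embryonic myosin heavy chain, was at 1.86 FPKM in the empty vector library and 4.57 FPKM in the Cacnb4 library, and Myh1 was 1.47 times lower, at 23.8 FPKM in the Cacnb4 library. Cardiac and hypertrophy markers had a median of -0.01 at percentile 70.7, with Gata6 at 4.97 and 8.98 FPKM and Tnnt2 at 214 and 309 FPKM. Calcium handling and signalling genes had a median of 0.01 at percentile 80.7 over 30 measured members. Smooth muscle markers had a median of -0.05 at percentile 59.2. Extracellular matrix and fibroblast genes had a median of 0.32 (95% interval 0.16 to 0.44), above all matched random lists, and 25 of 31 were above 0. Fibronectin, Fn1, was at 760 and 1286 FPKM, Ctgf at 646 and 1087 FPKM and Fbn1 at 23.1 and 39.5 FPKM, while Col6a2 was at 2.09 and 0.566 FPKM. The authors' deposited table marked Myh3 and Col6a2, with q-values of 0.0310 and 0.0371. From these lists it also marked single transcripts of Tnnt3, Slc8a1 and Itpr1, described below.

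Of the metabolic and housekeeping lists, oxidative phosphorylation had a median log2 ratio of -0.13 at percentile 1.53, with 52 of 58 members below 0. Cholesterol synthesis had a median of -0.11 at percentile 6.02, glycolysis and hypoxia one of -0.12 at percentile 13.5, ribosomal proteins one of -0.07 at percentile 93.8, and commonly used reference genes one of -0.12 at percentile 18.7. Vegfa, in the hypoxia list, was at 21.4 FPKM in the empty vector library and 41.5 FPKM in the Cacnb4 library. Sqle of cholesterol synthesis was at 40.4 and 27.3 FPKM. Most markers of other cell types were below 1 FPKM. Of 19 leukocyte, 11 endothelial and 14 neuronal and glial markers listed, 2 in each list were measured and 0 of these were 2-fold different, among them Cd14 at 8.76 and 9.61 FPKM, Egfl7 at 14.1 and 12.7 FPKM and Tubb3 at 24.3 and 23.5 FPKM.

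**Figure D3:**
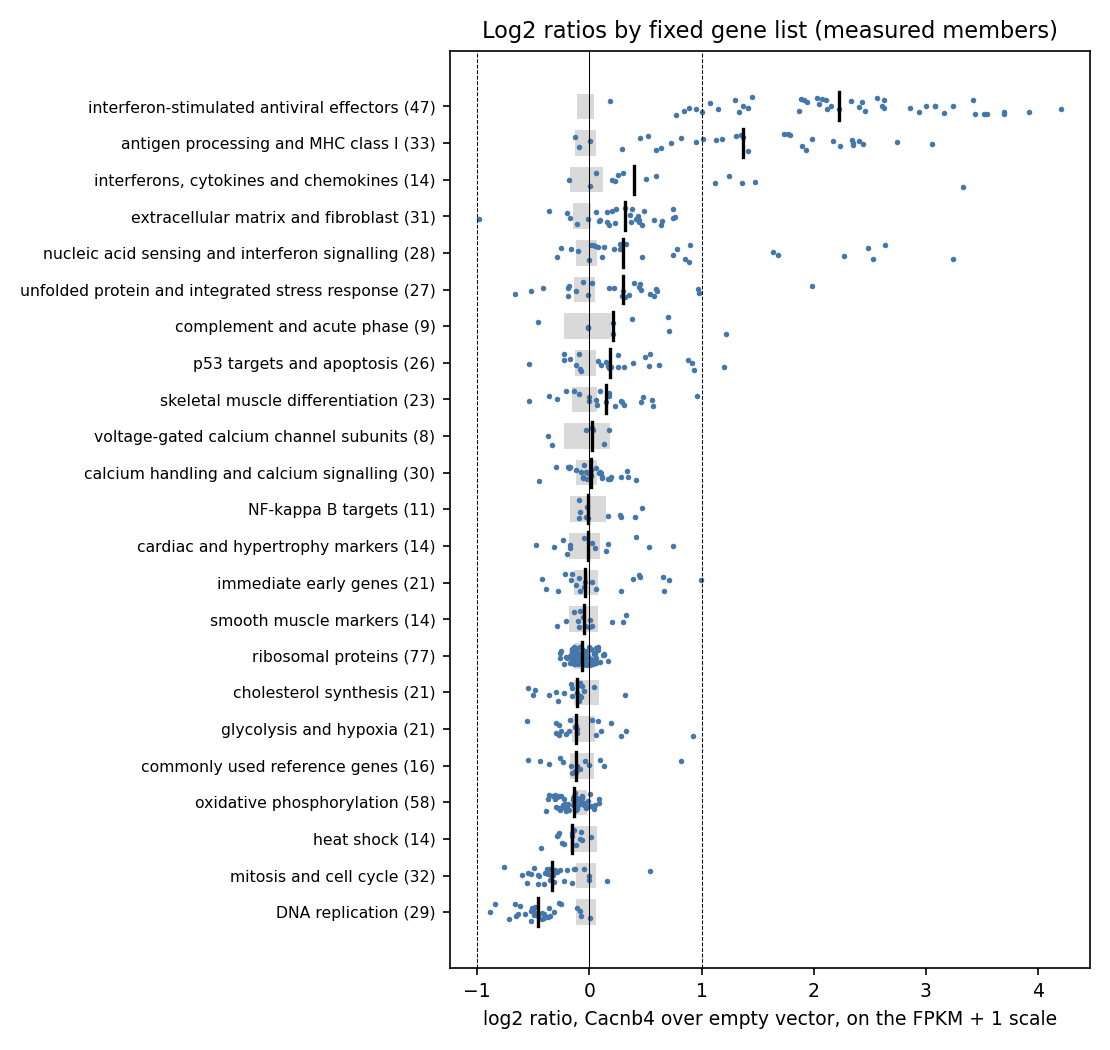
Log2 ratio of the Cacnb4 library over the empty vector library on the FPKM + 1 scale for each measured member (points) of the 23 fixed lists with at least 6 measured members, with the number measured in brackets. Black bars are list medians, grey bands hold the central 95% of medians of matched random lists, dashed lines mark 2-fold, and Cacnb4 is left out of the points but not of its list's median. The interferon-stimulated list has the highest median, 2.23, and DNA replication the lowest, -0.46.

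Over all 9539 measured genes, 185 were at least 2-fold higher in the Cacnb4 library and 103 at least 2-fold lower, and 97.0% lay within 2-fold. The median log2 ratio was -0.03. MicroRNA precursors held many of the places at both ends, with 39 of the 185 higher genes and 77 of the 103 lower genes. Without them the counts were 146 higher and 26 lower. Of the 185 higher genes, 42 were in the interferon-stimulated list, and 71 in that list, the sensing list or the antigen presentation list. The authors' deposited table marked 83 of the higher and 4 of the lower genes. The 12 highest log2 ratios were those of Cacnb4 and of microRNA precursors listed at 0 in the empty vector library, such as Mir93 at 196 FPKM in the Cacnb4 library. The lowest was Mir182, at 2079 FPKM in the empty vector library and listed at 0 in the Cacnb4 library. Its neighbours on chromosome 4, Mir96 at 255 FPKM and Mir183 at 162 FPKM in the empty vector library, were also listed at 0 in the Cacnb4 library. Of 170 measured precursors the authors' deposited table marked 0. Among other genes, MGC108823 was at 5.13 and 60.4 FPKM. The lowest of them was the small nuclear RNA gene LOC252890, at 295 FPKM in the empty vector library and listed at 0 in the Cacnb4 library. Cox7c is listed with the same locus, at 267 and 208 FPKM, so reads can be split between them. The authors' deposited table did not mark LOC252890. The potassium channel subunit Kcns3 was at 3.31 FPKM in the empty vector library and 0.0321 FPKM in the Cacnb4 library, and embryonic globin Hbe2 at 37.3 and 9.68 FPKM.

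The authors' deposited table marked 228 transcripts as significant between these 2 libraries, 221 higher and 7 lower in the Cacnb4 library. Of these, 99 carried a gene name, from 98 genes, with 94 higher and 5 lower. The 5 lower were Kcns3, Adamts19, Hbe2, Col6a2 and LOC689064, and all 5 are named because they are few. In the authors' deposited table, 5 of the higher named transcripts were listed at 0 in the empty vector library. Some marked transcripts differed from their gene's sum. For the sodium-calcium exchanger Slc8a1, the authors' deposited table gave 1 transcript at 0 and 5.03 FPKM, while the gene's sum was 9.15 and 7.92 FPKM. For the calcium release channel Itpr1 it gave 1 transcript at 1.14 and 5.72 FPKM, with a sum of 4.52 and 5.72 FPKM, and for Tnnt3 1 at 0 and 6.28 FPKM, with a sum of 9.04 and 11.4 FPKM. These 3 were chosen after their values were seen. Of 93 genes with a marked higher transcript, 10 were under 2-fold by the size rule. Of these, 7 had more than 1 transcript in the sum, and 3, Myh3, Pappa and Adamts15, had a single transcript and came under the threshold through the added 1 FPKM. Pappa and Adamts15 are named after their values were seen.

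For the higher genes, the authors' deposited table of pathways listed 10 KEGG pathways, of which 3 had a Benjamini-adjusted p-value below 0.05. RIG-I-like receptor signalling had 6 genes in the authors' deposited table, with a 17.5-fold enrichment and an adjusted p-value of 0.000775. Cytosolic DNA sensing had 5 genes there, with a 19.0-fold enrichment and an adjusted p-value of 0.00252 by the authors' deposited table. Ddx58, Irf7 and Cxcl10 are named for both of these pathways, so they are not separate results. Antigen processing and presentation had a count of 5 genes, with a 9.93-fold enrichment and an adjusted p-value of 0.0202 in the authors' deposited table. That table names 6 symbols for it, of which RT1-A1, RT1-A2, RT1-CE10 and RT1-N3 belong to the near-copy RT1 genes. For the lower genes the deposited sheet named no pathway.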

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

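The windows and groupings of transcripts without a gene name described here were all chosen after the data were seen, and no technical or biological explanation was tested for them. They stand here because the comparisons by gene symbol do not use such transcripts, and many were higher than in the empty vector library.

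Of the 129 unnamed transcripts marked in the authors' deposited table, 127 were higher in the Cacnb4 library. Joined where they lay within 100 kb of each other, the unnamed marked transcripts formed 36 groups, and 10 groups with 4 or more held 88 of them. The biggest group lay on chromosome 10 from 108781676 to 108862926, between Rbfox3 and Nptx1, and held 30 transcripts marked as higher. All 58 unnamed transcripts in that stretch were higher in the Cacnb4 library, and the median ratio of the marked ones was 9.29. A group of 10 lay on chromosome 2 from 240482936 to 240509351 between the guanylate-binding protein genes Gbp5 and Gbp2, with a median ratio of 9.87. The next groups held 9 on chromosome 4 between Tbxas1 and Rab19, with a median ratio of 4.11, 8 on chromosome 7 between Plec and Grina, with 7.75, and 7 on chromosome 1 beside Plekha7, with 2.71. Of 2 groups of 6 on chromosome 10, 1 lay around Igtp, with 7.74, and 1 between Slc13a5 and Fbxo39, with 5.30. Neighbouring unnamed transcripts can be parts of 1 gene, so these are not counts of genes.

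Near Cacnb4, an unnamed transcript on chromosome 3 from 34192829 to 34192923 was at 232 FPKM in the empty vector library and 610088 FPKM in the Cacnb4 library. A second, from 34193346 to 34193413, was at 95.1 and 110090 FPKM. The authors' deposited table marked both, and their ratios were 2629 and 1158. They lie 121 kb beyond the end of Cacnb4, before Stam2. FPKM at features this short is imprecise and, being scaled to length, does not rank against that of longer genes. On the other side, all 24 unnamed transcripts within 500 kb were higher in the Cacnb4 library, by up to 5.57 times with a median ratio of 2.07, from 33597667 to 33704071 and 230 kb from Cacnb4. The authors' deposited table marked 0 of these 24.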

How the results depend on the processing

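Leaving out microRNA precursors was chosen after the data were seen, and the other settings before. It moved the count of genes at least 2-fold lower from 103 to 26, which follows from removing those genes. The count of higher genes ran from 125 with a pseudocount of 5 FPKM to 244 with one of 0.1 FPKM, within 1.5 times of 185, and with 0.1 FPKM all 185 remained. The log2 ratio of Cacnb4 was 10.45 with a pseudocount of 0.1 FPKM, 9.39 with 5 FPKM and 10.22 after rescaling, and the construction of each setting shows the cause. The authors' calls numbered 161 at q below 0.01. Of 182 medians of lists under an alternative, 162 lay within the list's reported 95% interval or equalled its reported median. The other 20 did neither, most of them in lists too small for an interval. With a pseudocount of 5 FPKM, the median was 1.85 for the interferon-stimulated list and 0.94 for antigen presentation, both below their intervals. After rescaling it was -0.0765 for cholesterol synthesis and -0.0976 for oxidative phosphorylation, both above their intervals. The sign changed in 9 of the 182, in the NF-kappa B, calcium handling, cardiac and immediate early lists, whose intervals include 0. It changed in 0 of the 12 lists whose interval excludes 0. The filter moved some medians by over 1.5 times, and so did some other settings. Only examples for the filter are given here. With none, the median was 0.06 against 0.40 for interferons, cytokines and chemokines, 0.06 against 0.15 for skeletal muscle and 0.0013 against 0.22 for leukocyte markers, and with a minimum of 5 FPKM it was 0.71 against 0.21 for complement. The rescaling factor was 0.976. Keeping genes with a failed transcript could not be run, since the table used here has no such mark. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits low and short features most, since a few reads set their FPKM.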

Other observations

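The gene groups and single genes in the next 2 paragraphs, except Tmprss2, and all tests below apart from the one on short features, were chosen after the results were seen.

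Within the list of the unfolded protein and integrated stress response, the members went both ways. Beside Atf3, Chac1 and Trib3, the transcription factor Ddit3 was at 100.2 FPKM in the empty vector library and 152 FPKM in the Cacnb4 library, and Shmt2 of serine metabolism at 69.6 and 106 FPKM. Among folding factors of the endoplasmic reticulum, Manf was at 126 and 87.4 FPKM, and Hspa5, the main chaperone there, at 342 and 347 FPKM. No difference between parts of the list was tested.

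The 5 measured beta-globin genes were all lower in the Cacnb4 library, by 3.25 to 3.85 times. They lie on chromosome 1 from 161578126 to 161649279, and Hbb, Hbb-b1 and LOC100134871 are listed with the same locus. The genes also share sequence, so they are not independent. Hbb was at 59.9 and 18.0 FPKM, and the authors' deposited table marked 2 of the 5. Higher genes outside the fixed lists included Cd274, which encodes PD-L1, at 1.28 and 12.1 FPKM, and the protease Tmprss2 at 0.917 and 12.8 FPKM. They also included the cytosolic exonuclease Trex1 at 12.7 and 40.9 FPKM, and the sodium-activated potassium channel Kcnt1 at 2.96 and 18.2 FPKM. Spry1, an inhibitor of growth factor signals, was at 7.72 and 44.5 FPKM, with no transcript marked in the authors' deposited table.

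For the interferon-stimulated list, a scale factor would move every gene of the Cacnb4 library alike. The 7101 well expressed genes outside the list had a median log2 ratio of -0.0349 (95% interval -0.0403 to -0.0290), far from the list's interval of 1.94 to 2.62. This argues against scaling as the cause. The list's place above all matched random lists already held this, so it is not separate support. Leukocytes in the culture would bring their abundant transcripts, but the 19 listed markers had a median of 0.0846 FPKM in the Cacnb4 library, and 17 of them were under 1 FPKM. A difference between the 2 transfected cultures other than the insert, such as in plasmid preparation or dose, cannot be told apart from an effect of Cacnb4, because there was 1 library per group. Either could be the source of the pattern.

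The microRNA precursors at both ends of the ranking may reflect few reads on very short features. Among unnamed transcripts, the interquartile range of log2 ratios was 1.21 at 2559 loci of 120 bases or less and 0.493 at 2323 loci over 500 bases, 2.45 times as wide. The median precursor locus was 105.5 bases long, and 58 of the 170 were listed at 0 in 1 library. Some precursors at the ends are listed at longer loci, such as Mir93 on chromosome 12 from 17607249 to 17614508. A listed locus can be shared by several transcripts, as for LOC252890 and Cox7c, so it need not be the precursor's own length. The comparison of short and long loci went by listed locus, so it cannot tell whether these precursors are short features. Precursors in 1 cluster could also move together, as the neighbours Mir182, Mir96 and Mir183 did, all listed at 0 in the Cacnb4 library. Of 37 pairs within 10 kb that were both beyond 2-fold, 70.3% went the same way, against 38.7% to 73.2% after shuffling, so this stays open.

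The lower values of the DNA replication and mitosis lists were set against scaling and against a trend with expression level. The pooled median was -0.38 (95% interval -0.46 to -0.33) over 61 genes, of which 58 were below 0. The 7072 well expressed genes outside the lists had a median of -0.0320 (95% interval -0.0378 to -0.0268). Over 20 bins of expression level, the lowest median of genes outside the lists was -0.10. Both values argue against these explanations as the whole cause. The lists' place below all random lists matched on expression already held this, so the values are not separate support. Slower growth of the culture with Cacnb4 is 1 possible explanation, but differing cell density at harvest would look alike, and with 1 library per group neither was tested.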
